A study of Caenorhabditis elegans with 4 samples.

How the data were processed

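The series measured where the tagged protein EGL-27::GFP lies on DNA in fed larvae of the L1 stage of the nematode Caenorhabditis elegans. EGL-27 is a nuclear protein related to the MTA proteins of chromatin remodelling complexes, with a GATA-type zinc finger. Per the labels, the hermaphrodites of strain OP177 carried an egl-27 transgene fused to EGFP, with TY1 and FLAG tags, introduced by bombardment into an unc-119 mutant together with an unc-119 copy. Worms were grown at 20 °C on a bacterial lawn, crosslinked with 2% formaldehyde and sonicated, and DNA bound by GFP-tagged protein was recovered with a goat antibody against GFP, per the labels' protocols. The labels give 4 samples, which form 2 groups: 2 libraries of anti-GFP ChIP DNA and 2 libraries of input DNA, numbered as replicates 1 and 2 in each group. Nothing in the labels says whether the replicates came from separate cultures.

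The processed data were a single list of binding regions for all 4 libraries together. PeakSeq, a program that scores regions by comparing ChIP tags with scaled input tags, is named as the source of every region, and WormBase WS180 as the genome build, per the file headers. For each region the deposited list gives the first and last base and the authors' q-value, in general a p-value corrected for the number of tests. The aligner, the number of reads of each library, the input scaling and the settings of the caller are not given in the sources used here. The depth of each library is therefore unknown here, and no value of a single library was used. Since both replicates were combined before the regions were called, no test of ChIP against input across replicates was possible, and the q-values carry no information on the spread between replicates. A list of this kind also holds no information on sequence that did not pass the authors' threshold, and how far regions lie apart or join depends on the caller's merging rule. The 3728 listed regions do not overlap, and the smallest gap between neighbours was 202 bp.

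All coordinates are those of the list, counted from 1, in WS180. The only reference used was a gene table of another build, WBcel235, so no coordinate of it was combined with the list. It served for the chromosome on which a named gene lies and for the number of protein-coding genes per chromosome, 19971 on the 6 nuclear chromosomes. For that reason the planned tests of distance to gene starts, of 25 fixed gene lists, of a GATA-type motif, and of the q-value against motif and gene distance were not run, and no region is assigned to a gene here. The regions named in the text follow a rule fixed before the data were examined: without an annotation of the build, the 10 regions with the smallest q-values and the 5 widest regions. Other regions and the stretches of regions were chosen after their values were seen.

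Chromosome length was taken as the last listed base of each chromosome, which sums to 100040987 bp. Counts per chromosome were compared with length by a two-sided Monte Carlo multinomial test with 100000 draws and by exact binomial tests, Benjamini-Hochberg adjusted over 6 chromosomes, with an adjusted p threshold of 0.05. Both treat regions as independent, which neighbouring regions are not. Whole blocks of 100 kb, and of 1 Mb, were therefore also permuted over the chromosomes 10000 times, a choice made after the data were seen. The expected share of a chromosome was then its number of blocks, with the partly filled last block counted as whole. The share of region midpoints in the central 33.3% of each chromosome was compared with 10000 random circular shifts per chromosome, which keep the spacing of regions. Distances between neighbouring midpoints were compared with 1000 uniform placements per chromosome. Regions separated by gaps of up to 2 kb were joined into stretches. The correlation of width with −log10 q was tested with 100000 permutations. Alternatives were the better-scored part of the list, merging of regions within 500 bp, covered base pairs in place of counts, gene number in place of length, a wider centre and other distances for neighbours.

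The products of q-value and list rank were also compared with binomial tails, as described with the other observations. Each product was matched, with a relative tolerance of 1e-08, to a whole number of tested regions times the lower tail of a binomial distribution with share 0.5, for sums of 8 to 6000 tags. Numbers of tested regions from 3728 to 20000 were scanned on the 101 levels, with sums of up to 200 tags, that at least 8 regions shared. Intervals on tag ratios are exact 95% binomial intervals that take the scaled input tags as counts. They cover counting error only, as far as that assumption holds.

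The tests were checked on simulated data. With 5000 simulated tested regions, the scan returned 5000, and 99.7% of the tag pairs of 2363 listed regions were recovered, with 0 recovered wrongly. The simulated q-values were made with the same binomial formula. This checks the matching, and does not show that the deposited q-values follow the formula. Of 20 uniform lists of 3728 regions, 1 was called in the multinomial test of all chromosomes, 0 in the test of the centre and 1 in the spacing test. False calls of the exact binomial tests were not counted. Regions of these lists were placed independently, unlike those of the real list. Neither chromosome test was run on clustered lists without an excess, and the permutation of blocks was not checked. With 150 regions moved to the middle of X, the adjusted exact binomial test of X called 20 of 20 lists and the test of the centre 5 of 20. With 300 regions placed beside others, the spacing test called 20 of 20. The search for runs of high input called 0 of 20 lists without a run and 20 of 20 with a run of 10 regions at 2 times the input. Input in these lists was drawn independently for each region, so false calls where neighbours share coverage were not checked. The runs found in the data were weaker than the simulated run, with median excesses of 1.54-fold on II and 1.64-fold on III. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.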

Results

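Binding of EGL-27::GFP was profiled by ChIP-seq in fed L1 larvae, from 2 ChIP libraries and 2 input libraries. The data were 3728 binding regions called on all libraries together, each with a q-value for ChIP over input. As no values per replicate were used here, no error between replicates can be given for any of them, and the tests that follow treat regions, not animals or libraries, as the units. The depth behind each region was not stated.

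The comparison of ChIP with input DNA asks where the tagged protein is enriched on the genome. Enriched regions were found on all 5 autosomes and on X, and together they covered 986357 bp, or 0.986% of the sequence spanned. The deposited q-values had a median of 0.00101 and all lay under 0.01. They reached below 0.001 in 1848 regions, below 1e-05 in 745, below 1e-10 in 223 and below 1e-20 in 54. Regions were narrow, with a median width of 218 bp and an upper quartile of 350 bp. The median was 330 bp in the 1864 regions with the smallest q-values and 441 bp in the best 932. There were 539 regions (14.5%) narrower than 50 bp, of which 31 were a single base pair wide, and 48 of 1 kb or more.

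The strongest region by q-value lay at X:11605379-11606501, with q = 1.95e-82. It was followed by IV:14032598-14034591 (q = 1.66e-58), III:12612237-12612901 (q = 4.86e-53) and I:9380086-9382229 (q = 4.91e-53). Chromosome III held 3 more of the 10 regions with the smallest q-values, at 8801323-8802484 (q = 5.93e-50), 4281674-4282724 (q = 1.16e-48) and 1920955-1921736 (q = 1.35e-46). The others were V:6227139-6228281 (q = 7.11e-41), II:11634839-11636205 (q = 1.80e-39) and X:6740574-6743167 (q = 2.66e-38). These 10 regions were 665 to 2594 bp wide. Each position is given in WS180, and what is annotated there was not analysed here.

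Wider regions had smaller q-values. Across the 3728 regions, width and −log10 q had a Pearson correlation of 0.65 and a Spearman correlation of 0.69, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. The caller's q-value depends on the number of tags in a region, and a wider region holds more tags, so a positive relation is partly built into the scoring and its p does not test a property of the binding. This is the only relation of the kind that was tested, and regions are not independent replicates. Regions narrower than 50 bp had a median q of 0.00444, and the smallest q among them was 2.28e-05. The 5 widest regions did not follow the ranking by q-value. Of these, 3 were neighbours on chromosome II, at 6840321-6846771 (6451 bp, q = 1.70e-37), 6834993-6839784 (4792 bp, q = 4.89e-32) and 6830611-6834557 (3947 bp, q = 4.20e-13). The other 2 were X:6740574-6743167 (2594 bp) and I:9380086-9382229 (2144 bp), both also among the 10 with the smallest q-values.

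**Figure D1:**
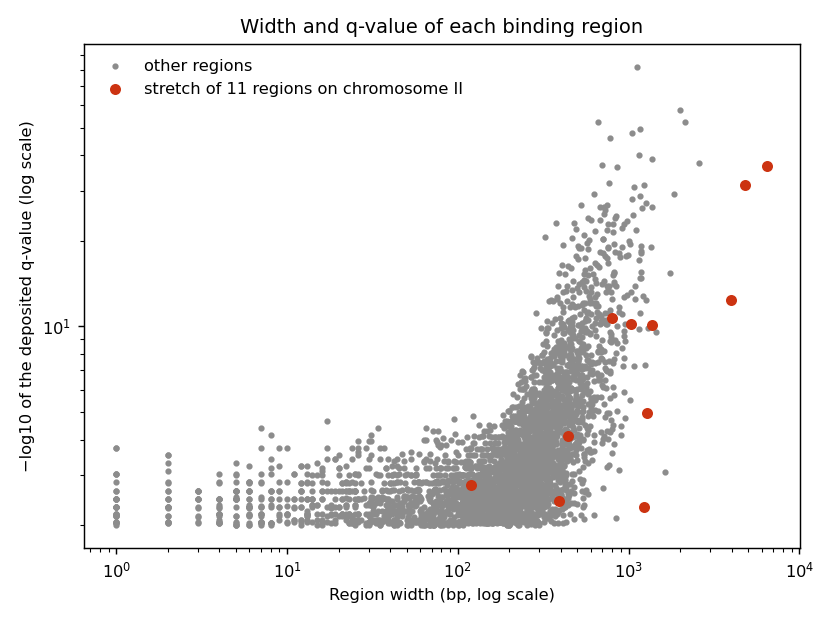
Each point is 1 of the 3728 regions, with its width in bp on the horizontal log axis and −log10 of the deposited q-value on the vertical log axis. Wider regions had smaller q-values (Spearman correlation 0.69), and the 11 regions of the largest stretch on chromosome II, in red, include the 3 widest, of 3947 to 6451 bp.

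Binding regions were spread unevenly over the chromosomes, with the highest density on chromosome III. It held 664 regions where its length predicted 513.2, a ratio of 1.29 (exact binomial test, adjusted p = 2.99e-11), or 48.2 regions per Mb. X held 729 regions against 659 expected, a ratio of 1.11 (exact binomial test, adjusted p = 0.00456) and 41.2 per Mb. Chromosomes V and II were below expectation in the same exact test, with 687 regions against 777.9 (ratio 0.883, adjusted p = 6.74e-04) and 498 against 568.9 (ratio 0.875, adjusted p = 0.00225). Chromosome IV was lower by less, with 601 regions against 651.1 (ratio 0.923, exact binomial adjusted p = 0.0372), and chromosome I, with 549 against 557.9, was not distinguishable from its length (adjusted p = 0.696). Over all 6 chromosomes the chi-square was 75.2, with a Monte Carlo p of 1e-05, the smallest possible with 100000 draws. The median width of the regions also differed, from 179 bp on V to 248 bp on X, with 207 bp on III. Whether sequence coverage, and so the power to call a region, differed between chromosomes was not tested.

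The counts were also tested with whole blocks of sequence as the units. In the permutation of 100 kb blocks, the excess on III (adjusted p = 6e-04) and X (adjusted p = 0.0479) and the deficit on V (adjusted p = 0.0291) and II (adjusted p = 0.0456) still passed, and IV did not (adjusted p = 0.147). In the permutation of 1 Mb blocks, III alone passed (ratio 1.30, adjusted p = 0.0018). The ratios of X (1.11), V (0.895) and II (0.852) stayed about as far from 1, with permutation adjusted p-values of 0.179, 0.179 and 0.133. Relative to the number of protein-coding genes on each chromosome, X had 1.43 times and III 1.35 times the expected regions, and V had 0.737 times and II 0.774 times. The corresponding adjusted p-values of the exact binomial tests were 1.82e-22, 5.58e-15, 3.12e-21 and 1.30e-10. Unlike the permutations, these tests treat regions as independent, so their p-values are too small for clustered regions. Blocks were not permuted against gene number. IV was at 0.981 times and was not called on that scale (exact binomial adjusted p = 0.627). By covered base pairs, X had the highest ratio to its length share, at 1.25 (permutation of 100 kb blocks, adjusted p = 0.0144), with III at 1.23 (adjusted p = 0.0432), and whether X and III differed was not tested. V was at 0.73 on that measure (permutation, adjusted p = 0.003), while II, at 0.955, and IV, at 0.905, were not called (permutation, adjusted p = 0.692 and 0.372).

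**Figure D2:**
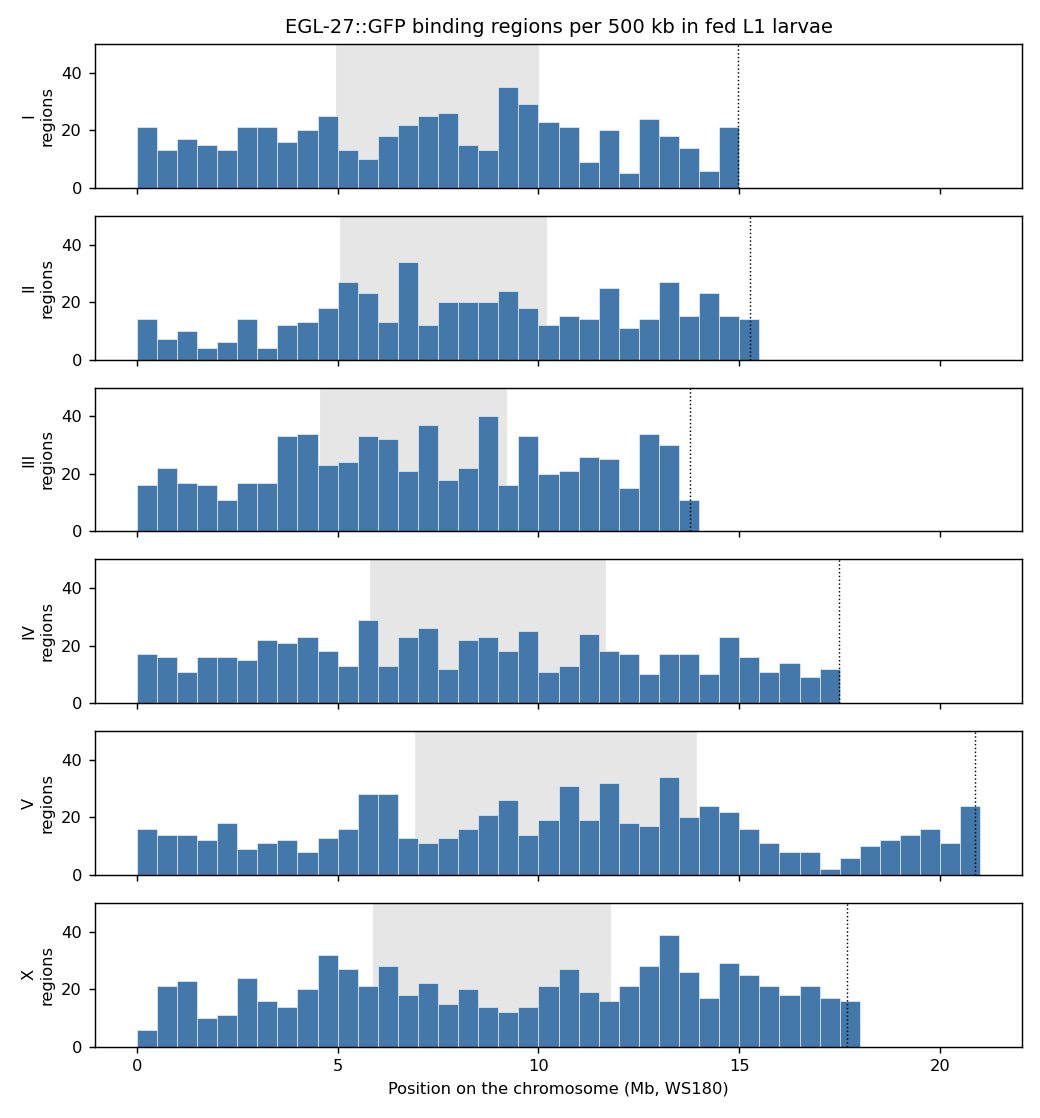
Bars count the binding regions in each 500 kb bin (vertical axis) along the 6 chromosomes (horizontal axis, Mb in WS180), with the central 33.3% shaded and the last listed base dotted, so the last bin of a chromosome is partly filled. Chromosome III had the highest density, at 48.2 regions per Mb, and chromosome II the lowest, at 32.6.

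The autosomes of this nematode have gene-dense centres and more repetitive arms, so the position along the chromosome was compared as well. The central 33.3% of the chromosomes held 1403 regions, or 37.6%, against a mean of 33.3% when the regions were shifted around the chromosomes (95% of shifts between 29.8% and 37.2%, two-sided permutation p = 0.025). The central 50% held 57.3% against 50.03% (permutation p = 2e-04). The shifts take no account of gene density or repeats along the chromosome. Whether either accounts for the excess in the centre was not tested. The share in the central 33.3% was highest on V (42.8%) and II (42.2%), between 36.9% and 37.4% on I, III and IV, and lowest on X (30.7%). No chromosome passed the test by itself, with adjusted p-values between 0.561 and 0.581, and whether X differed from the autosomes was not tested. For the 2999 autosomal regions alone the share was 39.3%, against 33.4% in the shifts (permutation p = 0.0052), a comparison chosen after the data were seen.

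EGL-27::GFP regions lay closer together than regions placed at random. Neighbouring midpoints were 13633 bp apart in the median, against 18365 ± 309 bp (SD of 1000 placements). Neighbours within 2 kb made up 17.1% of all pairs, against 7.30% ± 0.41, and both differences had a two-sided permutation p of 0.002, the smallest that 1000 placements can give. When each region was placed only within its own 100 kb block, the expected values moved to 16025 ± 268 bp and 8.90% ± 0.42, with the same p. Joined over gaps of up to 2 kb, the list formed 3017 stretches. Of these, 2525 were single regions and 492 held 2 or more, with 1203 regions (32.3%) between them.

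At II:6825715-6853622, 11 regions covered 21831 of 27908 bp, and the 3 widest regions of the list lay within it. A stretch at II:14036757-14046603 held 8 regions, and stretches at X:12869968-12878257 and V:13654091-13660667 held 7 each. There were 13 stretches of 6 or more regions. Those at V:6224353-6233302 and X:6736215-6745716 each had 6 and each included a region among the 10 with the smallest q-values. The transgene of the strain carries egl-27, which lies on chromosome II, and unc-119, which lies on chromosome III. Whether the stretch on II contains egl-27 was not tested, since no WS180 annotation was used here.

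**Figure D3:**
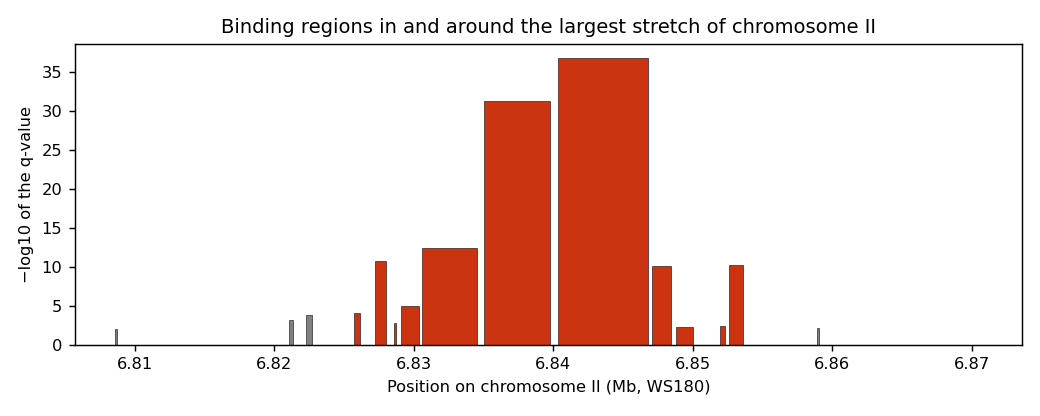
Binding regions in and around the largest stretch of chromosome II, drawn to scale, with position in Mb (WS180) on the horizontal axis and −log10 of the deposited q-value as bar height. Red bars are the 11 regions of the stretch, of which the widest spans 6451 bp, and grey bars are regions outside it.

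The ranking by q-value was compared between chromosomes through the 100 regions with the smallest q-values, a comparison chosen after the data were seen. X held 29 of them, against 19.3% of the other 3628 regions (odds ratio 1.71, Fisher's exact test p = 0.0208, adjusted over 6 chromosomes 0.079). IV held 8, against 16.3% of the others (odds ratio 0.445, Fisher's exact test p = 0.0263, adjusted 0.079). Neither passed after adjustment, and the adjusted p-values of the other chromosomes were 0.123 or higher.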

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

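The permutation of blocks for the counts, the autosomes alone, the list without the 11-region stretch, the placement within 100 kb blocks and every setting of the tag counts and input runs were chosen after the data were seen, and the other alternatives before; covered base pairs were planned, and their test by 100 kb blocks was chosen later. No paired analysis was possible because the list joins both replicates and gives no value per library, and leaving out a replicate was not possible for the same reason. The planned tests of gene starts, gene lists, GATA-type motif, and q-value with position were not run, with their alternatives, because no reference of the list's build was used. Of 89 values recomputed, 10 lost the call, 4 changed direction and 4 values without a test moved. The other 71 kept their direction and side of the threshold or, for values without a test, stayed within 1.5 times (counts) or within the 95% binomial interval of the median (width, 211 to 226 bp). They include the merging of touching regions, which could change nothing because the smallest gap was 202 bp. For the better-scored 50% and 25%, the counts moved by construction to 1864 and 932 regions, and the median width moved to 330 and 441 bp. With the better-scored 50% the median distance between neighbours was 29287 bp, against 36498 bp placed at random, where fewer regions lie further apart by construction. Chromosome IV lost its call with the better-scored 50% (ratio 0.9645), with regions within 500 bp merged (0.9311), by covered base pairs (0.9046), against gene number (0.9813), and with 100 kb (0.9231) and 1 Mb blocks (0.9135). Chromosome II lost its call by covered base pairs (0.9552) and, with 1 Mb blocks, so did II (0.8516), V (0.8951) and X (1.108). Chromosome I, which was never called, changed from just below to just above its expectation with the better-scored 50% (1.032), by covered base pairs (1.036), against gene number (1.022) and with 1 Mb blocks (1.001). Larger blocks leave fewer units to permute. They also count the partly filled last block of a chromosome as whole, which changes the expected count. The observed counts stayed the same with 1 Mb blocks, so the change on I, and the lower ratio on II, came from that expectation. The 11-region stretch on II held 2.21% of all covered base pairs, and covered base pairs without it were not compared. For the losses other than those with larger blocks, the cause was not tested. The call on III, the overall chromosome test, the excess in the centre, the close spacing and both runs of high input passed in every alternative run for them. The share in the central 33.3% ranged from 37.3% to 39.9% where that definition was kept. The unknown depth of each library limits what can be said of weak regions.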

Other observations

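The tests in this part were all chosen after the results they bear on were seen. If the tag counts described next are taken as read, they add the size of each enrichment to the q-values. The median region then held 42 ChIP tags (quartiles 28 and 64) and 15 scaled input tags (quartiles 8 and 24), a ratio of 3 (quartiles 2.52 and 3.71). Ratios were under 2 in 127 regions (3.43%) and 5 or more in 297 (8.01%). All are ratios of regions with q under 0.01, so a region with few tags was listed only if its ratio was high. By chromosome, regions on X had the most input tags, with a median of 19, and the lowest median ratio, 2.84. Those on V had the fewest, 12, and the highest median ratio, 3.2, and III had 14 and 3.14. Whether these differences bear on the counts per chromosome was not tested. The 3 highest ratios, of 22, 21 and 20, belonged to regions of 17, 7 and 8 bp with 1 input tag each. The region with the smallest q-value, X:11605379-11606501, had 459 ChIP and 47 input tags, a ratio of 9.77 (95% exact interval 7.22 to 13.5). III:12612237-12612901 had a ratio of 7.93 (5.72 to 11.3), with 325 and 41 tags, and III:1920955-1921736 a ratio of 7.27 (5.23 to 10.3), with 298 and 41. IV:14032598-14034591, second by q-value, had more ChIP tags, 519 against 116 in input, and a lower ratio of 4.47 (3.65 to 5.52). The intervals cover counting error only, and the input tags are scaled by the caller, so they are not a count of reads.

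The counts come from a regularity of the q-values. Multiplied by the rank in the list, they never fell from a line to the next and came back to the same levels many times. A candidate explanation is that each q-value is a number of tested regions times a binomial tail, divided by the rank. With 6924 tested regions, 100% of the 101 levels shared by at least 8 regions equalled such a tail within a tolerance of 1e-08, while the best of the other numbers between 3728 and 20000 matched 0.99%, which argues against chance matches. On that reading 53.8% of the tested regions were listed, and 3708 of the listed regions had a single pair of ChIP and input tags that gave their q-value. The other 20 had 2 pairs and are left out, 18 of them with 12 and 0 or 20 and 3 tags. No biological explanation applies, and the authors' own counts were not used here.

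The 11 regions of the stretch at II:6825715-6853622 held 2407 input and 4364 ChIP tags, a ratio of 1.81 (1.35 to 3.33 by region). The 41 other regions of 1 kb or more had a median ratio of 3.25 (quartiles 2.74 and 3.97). The stretch had 110.3 input tags per kb, 1.84 times the median of 59.96 (quartiles 53.98 and 69.9) of those 41 regions. Its own 7 regions of 1 kb or more ranged from 62.2 to 137.1 per kb, so the lowest, II:6852594-6853622, lay within those quartiles, as did the narrower II:6827189-6827984 at 67.8. Random orders of all regions of at least 200 bp argue against chance, with a permutation p of 0.0004 for the highest running median of 7 regions, a log2 input excess of 0.83, which windows wholly inside the stretch reached; the run of windows above the threshold was wider, at II:6822256-6968628, with 14 regions, 12 of them above expectation, and 4 of the 14 outside the stretch. Extra copies of the stretch in this strain, for example from the transgene, and sequence that the assembly holds in fewer copies than the genome both predict the high input, and only 1 of the 41 regions was denser than the stretch as a whole, V:264948-266579, with 593 ChIP and 477 input tags. These data do not separate these explanations, because input of a strain without the transgene was not analysed here, and no biological explanation was tested.

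A second run of high input lay at III:7153731-7335552. All 14 of its regions of at least 200 bp had more input than their width predicted, with a median log2 excess of 0.71 (95% bootstrap range 0.54 to 0.81), a median ratio of ChIP to input tags of 1.83 (1.67 to 3.25 by region) and a ratio of 2.12 of the summed tags. Random orders argue against chance here as well (permutation p = 0.0012, over the runs of all chromosomes). The median excess was 1.64-fold, above the 1.5-fold set as the prediction of extra copies, and the 95% range includes 1.5-fold. A run was built from windows with a running median log2 excess above 0.578, which is about 1.5-fold. The comparison was thus largely settled by the search and does not test the prediction, and the 95% range comes from the same selected regions. Extra copies cannot be told apart from other sources of high input, since the run was picked for its input. The search found runs on II and III alone, the highest running medians of the other 4 chromosomes having p-values of 0.672 or more, and unc-119 lies on III, but whether the run contains it was not tested.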
